A study of Homo sapiens with 12 samples.

How the data were processed

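Gene expression was measured on 12 single-colour Illumina expression beadchip arrays with 47231 probes. The arrays covered 2 human lymphoma cell lines, TMD8 and DOHH2, each treated with DMSO, the vehicle, or with the compound ST5589 at 300 nM, with 3 arrays in each of the 4 groups. Groups, doses and replicate numbers were taken from the sample labels. The exposure time and the origin of the replicates (separate cultures or not) are not given in the sources used here, so p-values measure only the spread between these arrays, which may be technical.

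Per the labels' protocols, total RNA was isolated on RNeasy columns, its integrity was checked on a Bioanalyzer, and biotin-labelled cRNA was made with the TotalPrep amplification kit. Per the submitters' processing notes, GenomeStudio was used, with no version given. The authors deposited a table of non-normalized probe intensity values on a linear scale and a table of processed log2 values. The normalization behind the authors' log2 values is not given in the sources used here. Within each of the 12 arrays these log2 values ranked the probes as the intensities did (Spearman correlation 1.000000 to the digits kept), every array had the same median to 2 decimals (6.67), and the values kept the direction of the intensities. They were used as an alternative only.

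The plan fixed before the data were examined was the neqc normalization and a filter on detection p-values. The deposited intensity table carries neither detection p-values nor control probes, so both were replaced. Background was corrected with normexp (saddle-point fit, offset 50) and arrays were quantile normalized on the log2 scale, with R 4.3.3 and limma 3.58.1. The background of each array was estimated as the mode of its intensities, with an SD mirrored from the values under the mode, and a probe counted as above background where it exceeded the mode by 2.33 SD. Probes above background in all 3 arrays of at least 1 group were kept, which left 20535 probes. Where a probe was not above background in any array of a group, a fold is given as "at least", from the mean of the bright group against, per array, the higher of the lowest signal above background and the probe's own signal.

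Gene names came from the platform annotation, updated through gene identifiers to current symbols. Of the 47231 probes, 30113 had 1 gene symbol, 8 had several and 17110 had none here; 30074 of the 30121 listed probes matched a current gene identifier. Of the kept probes, 15380 had 1 symbol and 5155 were unnamed and not tested. Each gene was represented by its kept probe with the highest mean over the 12 arrays, which gave 11419 genes, 3114 of them with more than 1 kept probe. No sample column was left unused, and no pair of arrays held identical values.

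Between arrays the median intensity lay between 90.0 and 113, the background mode between 86.2 and 106, and the share of probes above background between 38.0% and 46.1%. The number of arrays limits the precision: the median standard error of a log2 fold change within a line was 0.11.

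A single linear model with 1 coefficient per group was fitted to all 12 arrays with lmFit and eBayes, with no replicate block, and p-values were adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05. The contrasts were ST5589 against DMSO in each line, the difference of these effects (DOHH2 minus TMD8) and DOHH2 against TMD8 under DMSO. No control array was shared between the comparisons in the 2 lines. The arrays of each line lay on a chip of their own, so line and chip cannot be told apart. On each chip the DMSO arrays held the first 3 of the places used and the ST5589 arrays the rest, so treatment and place on the chip cannot be told apart within a line.

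Gene lists (23 lists with 525 distinct genes, of which 431 were tested) were fixed before the data were examined. 22 lists had enough tested members for a test; the list of T and NK cell markers had 1. They were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, with camera at an estimated correlation and fry as alternatives. The genes named were set by a rule fixed at the same time: AURKA, AURKB, CDKN1A, MDM2, MYC, CCNB1, PLK1 and CYP26A1 in any case; the 6 largest rises and 6 largest falls among called genes whose treated arrays all lay on a single side of the DMSO arrays; up to 3 called members of each list; and the 5 largest in each direction for the other contrasts. Uncharacterised genes and genes that mark sex were not named.

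The model fit was tested on simulated data over 11419 genes. In each comparison 67 genes were changed by 0.5 on the log2 scale, 67 by 1 and 66 by 2. The changes and independent normal noise for each gene were added to group means of normalized values. Normalization, the filter and deviations shared by the genes of an array were thus not simulated. The shares below are therefore not the power in the real arrays. For ST5589 against DMSO in TMD8 the fit recovered 70.1% of simulated log2 changes of 0.5, 95.5% of those of 1 and 100% of those of 2, with 5.85% false calls. In DOHH2 the shares were 61.2%, 98.5% and 100%, with 6.49% false calls. For the difference between lines they were 16.4%, 82.1% and 98.5%, with 5.76% false calls.

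The alternatives were other background corrections, median scaling, quantile normalization within each line, the authors' log2 values, other filters on dim probes, other ways to represent a gene, the arrays of a comparison alone, a replicate block, array weights, a trended and robust eBayes, other thresholds, and each array left out in turn. Figures were drawn with matplotlib 3.10.9.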

Results

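Transcript levels were measured in TMD8, a diffuse large B-cell lymphoma line of the activated B-cell-like type, and in DOHH2, a B-cell lymphoma line of germinal centre type, after ST5589 at 300 nM or DMSO. ST5589 is named in the labels as a derivative of ST1926 (adarotene), an atypical retinoid. Each of the 4 groups held 3 arrays, and 11419 genes were tested. All values are normalized log2 intensities, errors of fold changes are standard errors from limma, and adjusted p-values are Benjamini-Hochberg values from limma.

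The series names AURKA, the mitotic kinase Aurora A, as a gene lowered by the compound, so it is given first. In TMD8, AURKA was 11.24 ± 0.03 (SD, n = 3) under DMSO and 10.41 ± 0.05 (SD, n = 3) under ST5589. The log2 fold change was -0.84 ± 0.09 (limma adjusted p = 3.8e-04), and all 3 treated arrays lay below all 3 DMSO arrays. A further AURKA probe gave -0.93. In DOHH2, AURKA was 10.11 ± 0.05 (SD, n = 3) under DMSO and 9.66 ± 0.14 (SD, n = 3) under ST5589, a log2 fold change of -0.45 ± 0.09 that did not pass the threshold (limma adjusted p = 0.224), with the groups again not overlapping and the further probe at -0.48. The difference between the lines, 0.38 ± 0.12, did not pass either (limma adjusted p = 0.9998). With arrays scaled to a common median in place of quantile normalization, the TMD8 value was -1.05 and no longer passed (limma adjusted p = 0.318, against 6.8e-07 to 0.0161 over the other alternatives).

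**Figure D1:**
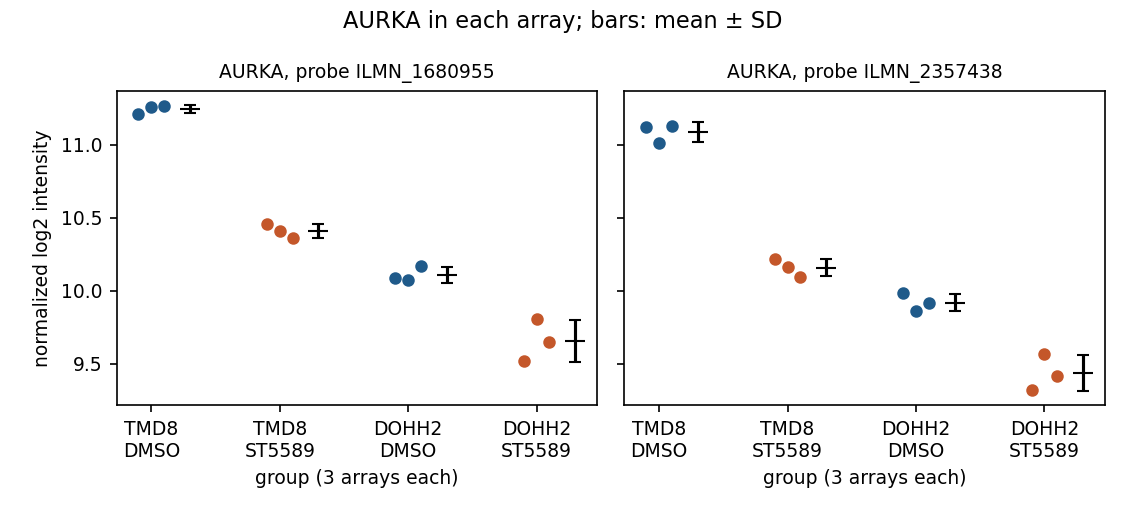
Normalized log2 intensity of AURKA (vertical axis) in each of the 3 arrays of the 4 groups (horizontal axis), with 1 panel per probe; points are arrays and bars the mean ± SD. With the probe used in the fit, TMD8 moved from 11.24 to 10.41 and DOHH2 from 10.11 to 9.66.

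In TMD8, genes of mitosis were lower and genes of DNA replication and p53 target genes higher under ST5589. 106 genes were called, 64 higher and 42 lower. Among protein-coding genes the largest falls were in KIF20A, a kinesin of cytokinesis (log2 fold change -1.23 ± 0.10), PLK1, a mitotic kinase (-1.15 ± 0.11), PIF1, a DNA helicase (-1.06 ± 0.15), and CENPA, the centromeric histone H3 variant (-0.96 ± 0.11). CCNB1, the mitotic cyclin B1, fell by 0.92 on the log2 scale (± 0.14). Among the rises were CDKN1A, the cell cycle inhibitor p21 (1.09 ± 0.19), and DDIT4, a stress-induced inhibitor of mTOR signalling (1.05 ± 0.11).

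Of the 41 members of the mitosis and spindle list, all tested, 19 were called lower and 0 higher, and 35 were lower when adjusted over the list alone. The median log2 fold change was -0.51 (camera adjusted p = 8.3e-56; adjusted p = 2.1e-04 with an estimated correlation). AURKB, the Aurora B kinase, was at -0.26 ± 0.09 and was not called (limma adjusted p = 0.355). Regrouping the TMD8 arrays without regard to treatment gave up to 8 lists at the preset correlation, against 9 with the real groups. A list called at that correlation alone thus does not set treatment apart from other groupings of the arrays.

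Of the 42 tested members of the DNA replication list, 5 were called higher and 0 lower, and 24 were higher when adjusted over the list alone. The median was 0.37 (camera adjusted p = 9.9e-26; adjusted p = 8.0e-05 with an estimated correlation). Examples were CCNE1, the G1/S cyclin E1 (0.61 ± 0.12), GINS2, a part of the replicative helicase (0.59 ± 0.12), and MCM4, another part of that helicase (0.55 ± 0.11). A second CCNE1 probe gave 0.24. CCNE1 and GINS2 lost their calls in 8 of 21 alternatives each, and MCM4 in 10 of 21. The DNA repair and checkpoint list also rose (median 0.20, camera adjusted p = 5.0e-07, and adjusted p = 0.0019 with an estimated correlation). Of its 25 tested members 1 was called, the exonuclease EXO1 (0.46 ± 0.09), which lost its call in 10 of 21 alternatives. When adjusted over the list alone, 6 were higher.

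Of the 27 tested p53 targets, 9 were called higher and 0 lower, and 14 were higher when adjusted over the list alone. The median was 0.30 (camera adjusted p = 5.6e-17; adjusted p = 0.0010 with an estimated correlation). Beside CDKN1A they included GADD45A, a growth arrest gene (0.87 ± 0.13), and PMAIP1, which encodes the BH3-only protein NOXA (0.77 ± 0.11). Further probes gave 1.01 for GADD45A and 0.22 for PMAIP1. MDM2, the ubiquitin ligase of p53, was at 0.37 ± 0.14 and was not called (limma adjusted p = 0.509).

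The list of unfolded protein and amino acid stress genes rose as well (median 0.10; camera adjusted p = 6.6e-06; adjusted p = 0.014 with an estimated correlation). Of its 29 tested members 4 were called higher and 0 lower, and 8 were higher and 1 lower when adjusted over the list alone. They were led by DDIT4, by ATF3, a stress-induced transcription factor (0.91 ± 0.11), and by DDIT3, which encodes CHOP (0.89 ± 0.16). With an estimated correlation and without TMD8 DMSO array 1, DOHH2 DMSO array 1 and DOHH2 ST5589 array 3, the list no longer passed (adjusted p = 0.0852).

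4 further lists passed with the preset correlation and not with an estimated one. The BCL2 family rose, with 2 of 14 members called, PMAIP1 and BAX (camera adjusted p = 0.077 with an estimated correlation). BAX, a pro-apoptotic member, was at 0.64 ± 0.14, with 0.15 from a second probe. Both called members are also in the p53 target list, so this rise is not separate from that of the p53 targets. For the BCL2 family fry gave an adjusted p = 0.00106. It tests whether genes of a list move one way without comparing them with other genes. NF-kB targets shifted up (median 0.14, 0 of 20 called; adjusted p = 0.22 with an estimated correlation). Heat shock and oxidative stress genes shifted down (median -0.08, 0 of 16 called; adjusted p = 0.22 with an estimated correlation). Replication-dependent histones shifted down (median -0.15; adjusted p = 0.28 with an estimated correlation), with H2AC6 called lower (-0.60 ± 0.12) and H4C2 called higher (1.09 ± 0.16; 2 of 3 DMSO arrays above background). Histone genes are near-identical copies, so the probe assignment is uncertain. Among the genes called here, BAX lost its call in 12 of 21 alternatives, H2AC6 in 8 of 20 and H4C2 in 0 of 20.

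The retinoic acid response list did not pass (12 tested, 0 called, median 0.07; camera adjusted p = 0.141), although fry gave an adjusted p = 0.0430 in the upward direction. CYP26A1, the retinoic acid hydroxylase that retinoids induce, was at 0.16 ± 0.09 (limma adjusted p = 0.781) and was above background in 1 of 3 DMSO and 3 of 3 ST5589 arrays. MYC was at 0.00 ± 0.11 (limma adjusted p = 0.999), with -0.31 from a second probe. Of the immediate early genes 1 of 14 was called, IER3 (0.74 ± 0.15), and the list did not pass (camera adjusted p = 0.865). IER3 lost its call in 9 of 20 alternatives. The lists of MYC and ribosome biogenesis, cholesterol synthesis, autophagy and lysosome, interferon response, antigen presentation, pan B cell, germinal centre and activated B cell genes, myeloid markers, stromal and epithelial markers and reference genes had 0 called members, and the lowest camera adjusted p among them was 0.0606.

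Among the called genes of TMD8, the largest changes were in small non-coding RNAs. RNU6ATAC and RNU4-2, RNAs of the minor and major spliceosome, rose by 2.54 ± 0.24 and 2.46 ± 0.26, RN7SK, which restrains the elongation factor P-TEFb, by 2.17 ± 0.28, and the H/ACA small nucleolar RNAs SNORA2B and SNORA74A by 2.12 ± 0.26 and 1.60 ± 0.29. RNY4, a Y RNA, and VTRNA1-1, a vault RNA, fell by 1.58 ± 0.21 and 1.45 ± 0.14 on the log2 scale. RIMBP3, a protein-coding gene, rose by 1.84 ± 0.28. Among the rises named here, the SD of the ST5589 arrays ran from 0.65 for RNU4-2 to 0.85 for SNORA74A. In the DMSO arrays it ran from 0.06 for RIMBP3 to 0.37 for RNU4-2. The limma errors pool the spread over all 4 groups, so for these rises they are smaller than the TMD8 arrays alone would give. Over the classes, 6 of 14 small nuclear RNAs and 14 of 79 H/ACA small nucleolar RNAs were called higher, against 0 of 90 C/D small nucleolar RNAs; the medians over all members were 1.27, 0.0864 and -0.0872. The median of the ribosomal RNA probes was 10.72, 10.72 and 10.67 in the DMSO arrays of TMD8 and 11.59, 13.12 and 11.94 in the ST5589 arrays, with 0 of 3 ribosomal RNA genes called. Several of these RNAs have many near-identical gene copies, so the gene behind a probe is uncertain.

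Before adjustment 833 genes in TMD8 had a p under 0.05, against 571 by chance, and 17.8% of genes had non-overlapping groups, against 10% by chance. The count of 106 fell to 66, 50 and 57 without DMSO array 1, 2 or 3 and to 60, 62 and 61 without ST5589 array 1, 2 or 3, and was 9 with arrays scaled to a common median.

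In DOHH2, 4 genes were called. ATF3 rose by 1.16 ± 0.11 (limma adjusted p = 5.0e-04) and INHBE, an inhibin subunit gene that responds to endoplasmic reticulum stress, by 0.77 ± 0.11 (limma adjusted p = 0.0343). DLGAP5 and KIF20A, both of the mitotic spindle, fell by 0.82 ± 0.13 and 0.68 ± 0.10 on the log2 scale (limma adjusted p = 0.0495 for each). Of the alternatives tried, DLGAP5 lost its call in 17 of 21, KIF20A in 14 of 21, INHBE in 11 of 20 and ATF3 in 2 of 21. CDKN1A was at 1.07 ± 0.19 and CCNB1 at -0.54 ± 0.14, neither called (limma adjusted p = 0.125 and 0.566); a second CDKN1A probe gave 0.15. PLK1 was at -0.24 ± 0.11, AURKB at -0.05 ± 0.09, MDM2 at 0.33 ± 0.14 and MYC at 0.13 ± 0.11, none of them called, and CYP26A1 was not well above background in either group.

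The mitosis and spindle list fell (median -0.34, 39 of 41 members negative; camera adjusted p = 3.6e-31; adjusted p = 0.0020 with an estimated correlation), with 2 members called and 19 lower when adjusted over the list alone. DNA replication genes rose (median 0.20; camera adjusted p = 4.2e-09; adjusted p = 0.0020 with an estimated correlation), with 0 of 42 called and 3 when adjusted over the list alone. The p53 targets rose (median 0.19; camera adjusted p = 4.2e-09; adjusted p = 0.0089 with an estimated correlation), with 0 of 27 called and 8 when adjusted over the list alone. Unfolded protein and amino acid stress genes rose (median 0.08; camera adjusted p = 9.9e-05; adjusted p = 0.033 with an estimated correlation), with 1 of 29 called, ATF3, 8 when adjusted over the list alone and 11 negative. Without the same 3 arrays this last list no longer passed with an estimated correlation (adjusted p = 0.101). Regrouping the DOHH2 arrays without regard to treatment gave up to 6 lists at the preset correlation, against 7 with the real groups.

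NF-kB targets and pan B cell genes shifted up and histones down with the preset correlation and not with an estimated one (adjusted p = 0.119, 0.0845 and 0.577 with an estimated correlation), with 0 members called; fry gave an adjusted p = 0.0465 for pan B cell genes. The retinoic acid response list did not pass (median 0.03; camera adjusted p = 0.699), nor did any of the other lists, of which the lowest camera adjusted p was 0.106; by fry the BCL2 family was at an adjusted p = 0.0465. CD5, the 1 tested T and NK cell marker, was at -0.06 ± 0.11 in TMD8 and -0.03 ± 0.11 in DOHH2.

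DOHH2 ST5589 array 2 carried signal from 35 probes that were bright in TMD8 and not above background in the other 5 DOHH2 arrays, at a median of 4.12% of the TMD8 signal. Before adjustment 545 genes had a p under 0.05, against 571 by chance, and 8.32% of genes had non-overlapping groups, against 10% by chance. The count of 4 was 3 without that array and 1 without any other array of DOHH2, and 0 with arrays scaled to a common median.

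The 4 genes called in DOHH2 were all called in TMD8 in the same direction. The 2 rises compared with 0.0112 expected for independent lists (Fisher's exact test, one-sided, p = 3.1e-05), and the 2 falls with 0.00736 (p = 1.3e-05, same test). Both contrasts shared the estimated spread of each gene from the same fit, so the calls were not independent and these p-values may be too low. Of the 42 genes called lower in TMD8, 40 were negative in DOHH2, with a median of -0.39 (camera p = 4.9e-45, and p = 3.1e-04 with an estimated correlation). Of the 64 called higher, 43 were positive in DOHH2, with a median of 0.06 (camera p = 1.9e-11, and p = 0.039 with an estimated correlation). The estimated correlation was 0.16 for the lower and 0.18 for the higher genes, against the preset 0.01, so the first p-value of each set is too low. The ST5589 arrays held the same places on both chips, so a place effect alike on both could also give such agreement between the lines. Across all 11419 genes, which are not independent replicates, the log2 fold changes of the lines correlated with a Pearson r of 0.37, and 62.2% had the same sign. The count of 4 shared genes was 4 without TMD8 DMSO array 1, 3 without DOHH2 ST5589 array 2, 2 without TMD8 ST5589 array 2 and 1 without any other array.

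**Figure D2:**
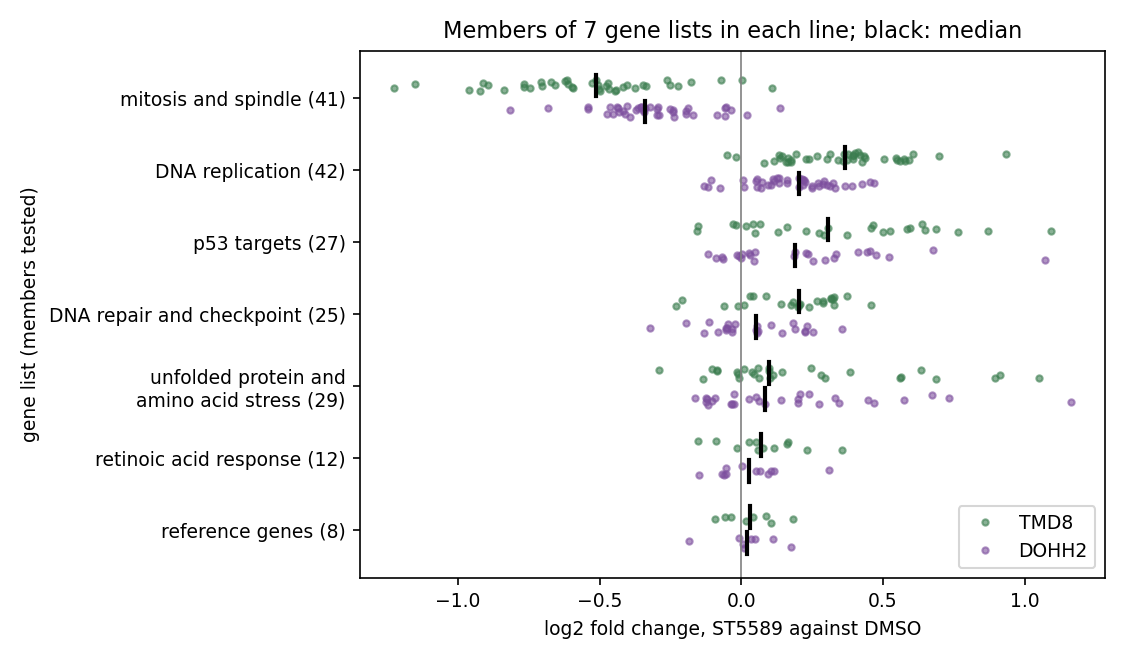
Log2 fold changes of ST5589 against DMSO (horizontal axis) for the tested members of 7 gene lists (vertical axis, number of members in brackets) in TMD8 (green) and DOHH2 (purple); each point is a gene and black bars are medians. The mitosis and spindle medians were -0.51 in TMD8 and -0.34 in DOHH2, and those of DNA replication 0.37 and 0.20.

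Tested directly, the change from DMSO to ST5589 arrays differed between the lines for 2 genes. VTRNA1-1 fell in TMD8 and was at 0.06 in DOHH2 (difference 1.503 ± 0.19, limma adjusted p = 0.0148). Under DMSO it was at 9.91 in TMD8 and 6.49 in DOHH2, where it lay only 0.26 above the lowest signal above background, so a fall of the TMD8 size was not measurable there. RNU6ATAC rose in TMD8 and was at -0.16 in DOHH2 (difference -2.71 ± 0.35, limma adjusted p = 0.0148). It is among the small nuclear RNAs higher in TMD8, for which RNA handling, place on the chip and the compound were not told apart. The difference of RNU6ATAC lost its call in 12 of 26 alternatives, and that of VTRNA1-1 in 7 of 26. The difference for PLK1, 0.91 ± 0.16, did not pass (limma adjusted p = 0.120). Under DMSO PLK1 was at 7.06 in DOHH2, where the lowest signal above background was 6.23. Its TMD8 fall of 1.15 was thus not fully measurable in DOHH2.

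Over the lists, 5 differences passed with the preset correlation, and 16 of 80 splits of the arrays that broke the treatment groups of both lines gave at least as many. Chance is thus not excluded for the list differences below. Mitosis and spindle genes fell less in DOHH2 (median of the differences per gene 0.26; camera adjusted p = 2.7e-13; adjusted p = 0.019 with an estimated correlation). DNA replication genes rose less (median -0.20; adjusted p = 0.0091 with an estimated correlation). DNA repair genes, which did not pass in DOHH2, differed as well (median -0.10; adjusted p = 0.018 with an estimated correlation). With an estimated correlation and without TMD8 DMSO array 1, DOHH2 DMSO array 1 and DOHH2 ST5589 array 3, the mitosis and DNA repair differences no longer passed (adjusted p = 0.0897 and 0.0793). The differences for p53 targets (median -0.11) and pan B cell genes (median 0.17) passed with the preset correlation and not with an estimated one (adjusted p = 0.074 with an estimated correlation for each). The other lists did not pass (lowest camera adjusted p = 0.152).

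The count of 2 was 18 without TMD8 ST5589 array 2 (1 higher, 17 lower), 4 without TMD8 ST5589 array 3, and 3 without TMD8 DMSO array 1. It was 1 without TMD8 DMSO array 3, TMD8 ST5589 array 1, DOHH2 DMSO array 2 or DOHH2 ST5589 array 2, and 0 without TMD8 DMSO array 2, DOHH2 DMSO array 1 or 3 or DOHH2 ST5589 array 1.

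**Figure D3:**
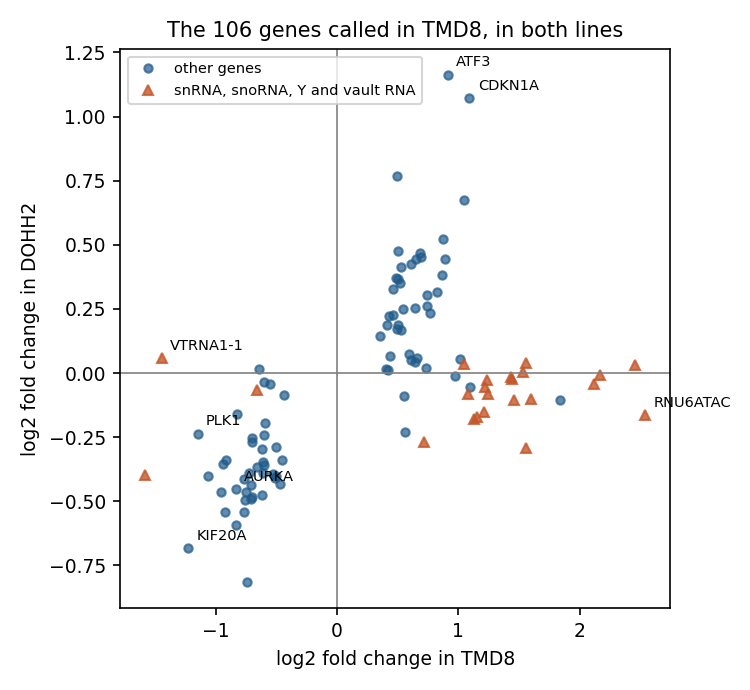
Log2 fold change of ST5589 against DMSO in TMD8 (horizontal axis) and DOHH2 (vertical axis) for the 106 genes called in TMD8; triangles are small nuclear, small nucleolar, Y and vault RNAs and circles all other genes. KIF20A lies at -1.23 and -0.68, and RNU6ATAC at 2.54 and -0.16.

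Under DMSO the lines differed in 6149 genes, 2982 higher in DOHH2 and 3167 lower. JCHAIN, the joining chain of secreted antibodies, was higher in DOHH2 by 6.32 ± 0.09 on the log2 scale. UCHL1, a ubiquitin hydrolase, was at least 58.8-fold higher, LAMP5 at least 22.5-fold and BBOX1, an enzyme of carnitine synthesis, at least 18.3-fold, since none was well above background in TMD8. SOCS2, a suppressor of cytokine signalling, was higher by 4.80 ± 0.13, and by 3.65 with a second probe. Lower in DOHH2 were GZMB, the protease granzyme B (at least 66.6-fold), CT45A1, a cancer-testis antigen (at least 71.4-fold, with -2.12 and -3.09 on the log2 scale from other probes), TCL1B (-6.23 ± 0.40) and the pseudogene NAPSB (-5.82 ± 0.31, and -4.10 with a second probe). CT45A3 was at -7.28 ± 0.73, above background in 1 of 3 DOHH2 DMSO arrays, with -6.64 and -6.80 from other probes. CT45A genes are near-identical, so their probes may not tell them apart. The errors of CT45A3, TCL1B and NAPSB draw on the spread in all 4 groups. For CT45A3 the SD was 2.30 in the DOHH2 ST5589 arrays, which are outside this comparison. It was 0.01 in the TMD8 DMSO arrays and 0.11 in the DOHH2 DMSO arrays.

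Among the lists, interferon response genes (15 of 20 called lower in DOHH2, 2 higher; median -1.68), NF-kB targets (15 of 20 lower, 3 higher), pan B cell genes (11 of 15 lower, 2 higher), activated B cell genes (13 of 19 lower, 5 higher) and histones (20 of 32 lower, 1 higher) shifted down with the preset correlation. Unfolded protein and amino acid stress genes (19 of 29 called higher, 5 lower) and DNA repair genes (13 of 25 higher, 2 lower) shifted up. Mitosis genes (22 of 41 called lower, 4 higher) and immediate early genes (9 of 14 lower, 1 higher) shifted down. None of these shifts passed with an estimated correlation (lowest adjusted p = 0.164), and the other lists did not pass with the preset correlation (lowest adjusted p = 0.0615). Among those other lists were germinal centre genes (7 of 13 called lower, 5 higher, median -0.65). Over all genes 6149 of 11419 were called, and the counts per list are to be read beside that share. Because each line had its own chip, line and chip cannot be told apart. With quantile normalization within each line, the share of calls higher in DOHH2 was 35.6% in place of 48.5%.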

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

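The tests of the mixed signal, the shifted arrays and the small RNAs were chosen after their results were seen; the counts over other splits of the arrays were set before, except that of the genes called in both lines and the division of splits by the groups they kept. Dixon's test for an outlying array was not run, since the groups held 3 arrays.

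The change from DMSO to ST5589 arrays differed between DOHH2 and TMD8 for 2 genes by the direct test of the difference: VTRNA1-1 (1.503), which under DMSO lay only 0.26 above the lowest signal above background in DOHH2 and so had little room to fall there, and RNU6ATAC (-2.71). Lists that passed this test had medians of the differences per gene of 0.26 for mitosis and spindle, -0.20 for DNA replication and -0.10 for DNA repair, and, with the preset but not an estimated correlation, -0.11 for p53 targets and 0.17 for pan B cell genes (adjusted p = 0.074 with an estimated correlation for each). Of 100 splits drawn within the lines, 12 gave at least 2 genes (highest other 91), but these were the 12 that kept the real TMD8 groups and so carried the TMD8 effect, and they decide nothing about chance. Of the 80 that broke the groups of both lines, 0 gave as many. Such splits put the change between treatment groups into the spread, which works against calls, so this count cannot exclude chance for the 2 genes. At least the 5 lists called were given by 34 splits (highest other 9), among them 16 of those 80, so chance is not excluded for the lists. For the 4 genes called in both lines, 88 of these splits called no gene in TMD8 and so fixed the count at 0; with the TMD8 groups kept, 1 of 20 splits of the DOHH2 arrays (mirrored splits counted apart, since direction mattered), the real one, gave as many (highest other 0), and 20 splits are too few for a share under 0.05.

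With 3 arrays against 3 there are only 10 splits, too few for a share under 0.05. In TMD8 1 split, the real one, gave 106 genes (highest other 0), and 1 gave 9 lists (highest other 8). Under DMSO 1 split gave the 6149 genes that differed between lines (highest other 0). In DOHH2 2 splits gave at least 4 genes (highest other 119), and 1 gave 7 lists (highest other 6). With so few splits, the splits cannot exclude chance for any of these counts, and the list counts of other splits came close to the real ones. Under DMSO, however, 6737 genes had a p under 0.05 between the lines before adjustment, against 571 by chance. Non-overlapping groups were seen for 59.0% of genes, against 10% by chance. These values argue against chance for the difference between the lines, though line and chip cannot be told apart. The split with 119 genes set DMSO array 1 and ST5589 arrays 2 and 3 against the rest, which points to a structure of the DOHH2 arrays other than treatment.

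In DOHH2 ST5589 array 2, all 35 probes that were bright in TMD8 and not above background in the other 5 DOHH2 arrays were above background, at a median of 4.12% of the TMD8 signal (quartiles 3.28% and 5.12%). A response of DOHH2 cells to ST5589 is argued against: over 38 such probes chosen from the DMSO arrays of DOHH2 without its treated arrays, the median was 4.21% in array 2 and the higher of those in the other treated arrays 0.0639%. A candidate explanation is TMD8 material mixed into this sample: the signals followed those of TMD8 with a Spearman correlation of 0.88 over the probes. Whether cells, RNA or labelled cRNA were mixed stays open.

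TMD8 DMSO array 1, DOHH2 DMSO array 1 and DOHH2 ST5589 array 3 lay at 0.44, -0.42 and -0.51 along a shared axis that held 45.9% of the variance left after the group means, and DOHH2 ST5589 array 1 at 0.40. The median of the ribosomal RNA probes was 10.29 in DOHH2 DMSO array 1 and 10.04 in ST5589 array 3, against 8.57 to 9.16 in the other DOHH2 arrays, and 10.72 in TMD8 DMSO array 1, against 10.72 and 10.67 in the other TMD8 DMSO arrays. The normalization used here is argued against as the cause of this axis, since the deviations of TMD8 DMSO array 1 and DOHH2 ST5589 array 3 correlated at -0.57 across genes in the log2 intensities with no correction or normalization too. A fixed effect of the place on the chip is argued against, since the arrays at the first place of the 2 chips deviated in opposite ways (correlation -0.32 across genes). RNA handling and labelling stay open, and no biological explanation was tested, because the arrays belong to the same groups as those they differ from.

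In TMD8, 20 small nuclear and nucleolar RNAs were called higher under ST5589, with a median log2 change of 1.44; over all members the medians were 1.27 for 14 small nuclear RNAs, 0.0864 for 79 H/ACA and -0.0872 for 90 C/D small nucleolar RNAs, and the 3 ribosomal RNA genes had a median change of 1.41 (0.80 to 2.99, 0 called), and their probes were highest in ST5589 array 2 (13.12). A single array is argued against as the cause: over all 14 small nuclear RNAs the median change was 1.87 in ST5589 array 2, and the lower of the medians in arrays 1 and 3 was 0.89. A rise of every kind of RNA without a poly(A) tail is argued against by 3 Y and vault RNAs called lower and 0 called higher of 7. A place effect alike on both chips is argued against by the median of -0.0689 of the same 20 RNAs in DOHH2. RNA handling that differed between the treated and control TMD8 samples, a place effect of the TMD8 chip alone and an effect of ST5589 in TMD8 all stay open.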

How the results depend on the processing

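Background from the mode of each array with an offset of 16 and the removal of the 3 shifted arrays were chosen after seeing the data. So were the residual component as a covariate and the lists without DOHH2 ST5589 array 2. The other alternatives were fixed before the data were examined. Counts are given in the order TMD8, DOHH2, difference between lines, both lines, lines under DMSO (main values 106, 4, 2, 4 and 6149), and those not given stayed within 1.5 times. The cause was not tested for any of these changes, except where fewer arrays, a stricter threshold or the residual component made them. Arrays scaled to a common median gave 9, 0, 0, 0 and 3923, all 9 TMD8 genes being among the 106, and AURKA in TMD8 at -1.05 no longer passed (adjusted p = 0.318, against 6.8e-07 to 0.0161 over the other alternatives). The authors' values gave 100 in TMD8, 98 of them shared, 1 for the difference and 2 in both lines. No background correction gave 1 in DOHH2, 1 for the difference and 1 in both lines. Background taken from the mode of each array, with an offset of 16, gave 2 in DOHH2 and 2 in both. Quantile normalization within each line gave 2 in DOHH2 and 2 in both, and 35.6% of the line differences higher in DOHH2 against 48.5%. The filter on all 12 arrays gave 1 and 1 in DOHH2 and both, the arrays compared alone 1 and 1, and a trended robust eBayes 2 and 2. Testing every probe gave 2 in both and 9836 between lines. Array weights gave 455 in TMD8 and 15 for the difference. A threshold of at least 2-fold gave 29, 1, 2, 0 and 1534, and an adjusted p under 0.01 gave 47, 1, 0 and 1 in the first 4. Without the 3 shifted arrays the counts were 160, 2, 1 and 2, and with the residual component 283, 10, 9 and 9. That component was taken from the deviations of these same arrays from their group means. As a covariate it cannot move a fold change, and it takes spread out of the fit. Its higher counts are thus no support for the calls, and named genes kept their direction under it by construction. Leaving out each array in turn gave 50 to 66 in TMD8, 1 to 3 in DOHH2, 0 to 18 for the difference, 1 to 4 in both and 5362 to 6305 between lines, and AURKA at -0.86 to -0.81 in TMD8 and -0.53 to -0.38 in DOHH2.

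Replicate numbers do not pair the arrays: the deviations of same-numbered DMSO and ST5589 arrays correlated at -0.15, -0.03 and -0.10 in TMD8 and -0.49, 0.00 and -0.25 in DOHH2, and not every array correlated best with its own number. A replicate block gave 40 genes in TMD8, 0 in DOHH2, 1 for the difference and 0 in both lines, and 4983 between lines.

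Lists called (9 in TMD8, 7 in DOHH2, 5 for the difference) numbered 5, 4 and 3 with an estimated correlation, 3 for the difference with fry, 8 for the difference without the 3 shifted arrays, and 4, 3 and 1 with both the shifted arrays left out and an estimated correlation. Over 528 list alternatives, 484 kept the side of the threshold, 31 lost the threshold and 13 gained it. A change of direction was counted only where the list passed in the main test or the alternative, and there were 0. Lists that passed in neither could change direction uncounted, as immediate early genes in TMD8 did (down by camera, up by fry). Over 1129 alternatives of 54 named results, 959 kept direction and side of the threshold, 154 lost the threshold, 6 gained it and 10 reversed. All 10 reversals were of MYC, which was not called: in TMD8 -0.26 with median scaling, -0.0006 in the authors' values, -0.15 as a mean of probes, -0.0326 with array weights, -0.0665 without the 3 shifted arrays, and -0.0665, -0.0017 and -0.0366 without TMD8 DMSO array 1, DMSO array 3 or ST5589 array 1 (-0.0665 to 0.0825 over all arrays left out in turn); in DOHH2 -0.0856 with median scaling and -0.0313 without the 3 shifted arrays. Signal over background limits what was tested: 38.0% to 46.1% of probes were above background in an array.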

Other observations

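The test of the cell cycle genes was chosen after its result was seen, and the genes named here were chosen after their values were seen. Called lower in TMD8 under ST5589, outside the fixed lists, were CDCA3, a trigger of mitotic entry (log2 fold change -0.76 ± 0.11), CDKN3, a phosphatase of cyclin-dependent kinases (-0.75 ± 0.12), KPNA2, an importin (-0.72 ± 0.10), RACGAP1, a part of the central spindle (-0.61 ± 0.13), and GTSE1, a microtubule-binding protein (-0.60 ± 0.08). CCNF, cyclin F, was at -0.64 ± 0.11 in TMD8 and 0.02 ± 0.11 in DOHH2, and the difference was not called (limma adjusted p = 0.495).

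CYP1A1, a cytochrome P450 that the aryl hydrocarbon receptor induces, rose in TMD8 (1.02 ± 0.12, limma adjusted p = 9.1e-04) and was not well above background in either group of DOHH2; the difference between the lines was not called (limma adjusted p = 0.120). AHRR, the repressor of the same receptor, was at 0.41 ± 0.09 in TMD8 (limma adjusted p = 0.0514) and TIPARP, another of its targets, at 0.22 ± 0.10 (limma adjusted p = 0.683), neither called. Other rises in TMD8 were E2F7, a repressor of the E2F family (0.83 ± 0.12), CX3CL1, a chemokine (0.73 ± 0.12), and CD1D, which presents lipid antigens (0.74 ± 0.13), and KLF2, a transcription factor of quiescent lymphocytes, fell (-0.55 ± 0.10).

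A hypothesis for the fall of mitotic genes in TMD8 was a general fall of cell cycle genes. It would need the DNA replication genes to fall too, but 40 of their 42 tested members had a positive log2 fold change in TMD8. A changed share of cells in each cell cycle phase stays open, untested.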
